A study of Ovis aries with 15 samples.

How the data were processed

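Native chromatin from perirenal fat of merino sheep fetuses (132 ± 1 days after conception, term 150 ± 3 days) and lambs was immunoprecipitated with 10 µg of antibody against H3K27me3, H3K27ac or H3K4me3, per the labels' protocols. The fragments were about 150 bp long and were sequenced as single-end reads of 50 bp on 1 of a pair of Illumina platforms, and which library ran on which is not given in the sources used here. The lambs' age is 80 days after birth in the series design and 89 ± 7 days in the growth protocol. Sex is not in the labels. The titles of the lamb libraries end in VEH and those of the fetal libraries do not, so whatever this tag stands for cannot be separated from stage. Reads were mapped to the Oar_v3.1 build with CLC Genomics Workbench 7.0, per the labels, and the submitters' processing notes name bedtools 2.19.0, edgeR and MACS without their roles. The pooled input library of each stage has no values in the tables, so no input was subtracted.

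The authors deposited a peak region table and a promoter table per mark. Per the file headers the peak tables hold expression values, which are whole numbers and so raw read counts per region, for 87272 regions of H3K27ac, 107166 of H3K27me3 and 66207 of H3K4me3. The values in the deposited promoter tables are a scaled signal: each library's values are whole multiples of its own step (the value of 1 read), from 0.369 to 0.571 for H3K27ac, 3.43 to 3.57 for H3K27me3 and 0.565 to 1.34 for H3K4me3. What the authors' factor is relative to, and the width of the promoter window, are not given in the sources used here. Dividing by the step gave whole reads (within 0.02 reads) at 99.97% or more of the values, and promoter reads per library ranged from 5061861 to 6257855 for H3K27ac, 324662 to 430345 for H3K27me3 and 2476065 to 17541582 for H3K4me3. Every promoter of a table reaches a deposited value of at least 50.2 in some library, so weak promoters are missing from the tables. A blank line of the H3K27me3 promoter table was left out. The authors also deposited a fold change, a p-value and an adjusted p-value per feature from a test headed EDGE, per the file headers. In the H3K27me3 promoter table the headers of fold change and p-value are exchanged, as their values show.

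Libraries were grouped by stage within each mark, from their labels. The lists, tests, alternatives and the rule for naming genes were fixed before the data were examined. The design foresaw edgeR on promoter counts, with limma if the values were scaled, which they were. Each library's promoter values were divided by its column total times its TMM factor, relative to the mean over libraries, which replaces the deposited scaling. They were then transformed as log2(value + 1) and tested with limma's trend method (limma 3.58.1). Peak counts were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, TMM scaling, filterByExpr). Both contrasts are lamb minus fetus, with Benjamini-Hochberg adjustment within each table and a threshold of 0.05. The replicate numbers name different animals in each stage and do not pair, so that stage was the only term. With 2 against 2 or 2 against 3 libraries, an exact permutation test of a single value cannot go below p = 0.333 or 0.2 (two-sided), and the adjusted p of edgeR and limma draw on the spread of all features instead.

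A set of 26 gene lists was tested on promoters with camera (preset correlation 0.01, at least 5 measured members, adjustment over the lists of a mark), and again with an estimated correlation and with fry, whose directional p tests a shift of the list itself. With an estimated correlation camera rests on the residual degrees of freedom, which are few with so few libraries. It then has little power, so a list that misses the threshold in that setting is left undecided. Members were matched by the symbols in the tables or by a unique synonym in a RefSeq gene table of the ARS-UI_Ramb_v3.0 assembly, used for names alone. The lists matched 29 of 34 brown fat genes, 17 of 19 white fat, 22 of 24 adipocyte, 25 of 27 fat synthesis, 42 of 62 respiratory chain, 33 of 39 HOX, 74 of 84 developmental, 30 of 34 cell cycle, 15 of 23 lymphocyte and 15 of 24 macrophage genes, and at least 10 genes of each remaining list except the mesothelial one, with 7 of 10. Genes measured in a pair of marks were compared by Spearman's and Pearson's correlation of their changes and by Fisher's exact test of shared calls, two-sided and adjusted over 12 pairs of directions. For each list the median change was ranked among 10000 random lists matched on mean level in 50 bins. Regions were called overlapping at 1 bp or, as an alternative, at 50% of the shorter region. No annotation of the Oar_v3.1 build was at hand, so regions were not linked to genes, apart from a 5S_rRNA copy whose promoter name carries coordinates.

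The genes picked for naming, a few of which are not printed, are 9 genes of thermogenesis and fat wherever a promoter table has them, the 6 largest changes each way among called promoters with a symbol and no overlap of the stages, up to 4 members per list, up to 4 genes per pair of marks and directions, and the 4 largest changes each way among regions. Promoters known by identifier alone (2103 for H3K27ac, 2264 for H3K4me3 and 1751 for H3K27me3) were tested but not named. A fold against a stage with no reads is a lower bound from a floor of 3 reads per library, which covers counting error only, since reads are not independent molecules.

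Alternatives were RLE scaling, column totals, DESeq2 1.42.0 (on recovered reads for promoters), a mean of at least 20 reads, no filter, a pseudocount of 0.1, an adjusted p under 0.01, each library left out in turn, and the replicate number as a block. When a library is left out, a stage with 1 library is assumed to vary like the other. Added after seeing the data were the deposited scaling with no further factor, edgeR on recovered reads, the authors' test at 0.05, scaling from regions outside X and the mitochondrial genome, leaving out the mitochondrial regions and 11 regions, shared by the marks, with at least 10 times the median read density in every library, and leaving out lambs 2 and 3 of H3K4me3. The limma fit of promoters, the edgeR fit of regions and camera at the preset correlation were tested on simulated counts with 200 changed features per table. The other steps were not simulated. At a true 2-fold change 94.0% were recovered for H3K27ac promoters, 35.8% for H3K27me3 and 19.4% for H3K4me3 promoters, and 86.6%, 5.97% and 8.96% for the regions of the same marks. Most real tables held far more calls than the simulated changes, which eases the adjusted threshold. These rates therefore hold for the simulated setting and are not those of the reported tests. Computation used R 4.3.3, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.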

Results

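Chromatin carrying 3 histone marks was sequenced from the fat around the kidney (perirenal adipose tissue) of merino sheep fetuses at 132 days of gestation and of lambs about 80 days after birth, a fat depot that turns from brown to white over this period. H3K27ac marks active promoters and enhancers, H3K4me3 marks promoters that are active or poised, and H3K27me3 marks genes held silent by Polycomb complexes. H3K27ac and H3K27me3 were each measured in 2 fetuses and 2 lambs, and H3K4me3 in 2 fetuses and 3 lambs. The animals numbered 1 and 2 of each stage were the same in all 3 marks. Reads in peak regions numbered 44096535 and 40308326 in the fetal and 43345057 and 34871674 in the lamb H3K27ac libraries. For H3K27me3 they numbered 10645917 and 10144027 in fetuses and 7522649 and 7233767 in lambs. For H3K4me3 they numbered 37544047 and 58333449 in fetuses, 41765806 in lamb 1, 13090548 in lamb 2 and 12482468 in lamb 3. The promoter tables held 13222 promoters for H3K27ac, 12922 for H3K4me3 and 6334 for H3K27me3. All changes are lamb minus fetus on the log2 scale, and means are scaled promoter values ± SD with n = 2 per stage, except n = 3 for H3K4me3 in lambs.

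H3K27ac addressed which active promoters gained or lost the mark between fetus and lamb. The promoter of UCP1, the protein that uncouples respiration to make heat, fell from 275 ± 8.29 to 143 ± 4.42 (log2 change -0.94, SE 0.15, limma adjusted p = 0.000242). PPARGC1A, a coactivator of mitochondrial and thermogenic genes, fell from 473 ± 46.7 to 257 ± 19.3 (log2 change -0.87, adjusted p = 0.00012). DIO2, which activates thyroid hormone within brown fat, fell from 286 ± 25 to 158 ± 8.59 (log2 change -0.85, adjusted p = 0.000461). ADRB3, the adrenergic receptor of adipocytes, fell from 243 ± 15.7 to 157 ± 31.6 (log2 change -0.64, adjusted p = 0.00847), and ADIPOQ, which encodes adiponectin, fell from 455 ± 43.6 to 342 ± 5.68 (log2 change -0.41, adjusted p = 0.0181). CIDEA, a lipid droplet protein, had 141 ± 4.50 in fetuses and 154 ± 1.03 in lambs (adjusted p = 0.643), and the leptin gene LEP had 140 ± 2.89 and 114 ± 1.47 (adjusted p = 0.266). PRDM16 was in the H3K27me3 table alone and PPARG was in none of the promoter tables. Of these promoters, ADRB3 lost its call without lamb 2 (adjusted p = 0.221), and the H3K27ac promoter of ADIPOQ lost its call without fetus 2 (adjusted p = 0.0679), lamb 1 (0.119) or lamb 2 (0.131). The H3K27ac promoter of ADRB3 kept its negative change in each of these settings. Of 4 groups of H3K27ac promoters by mean level, the strongest held 86 gains and 1489 losses (median change -0.31). The weakest held 558 gains and 83 losses (median 0.28). Single promoters were not set against promoters of like level, so small falls such as that of ADIPOQ may be part of this shift.

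**Figure D1:**
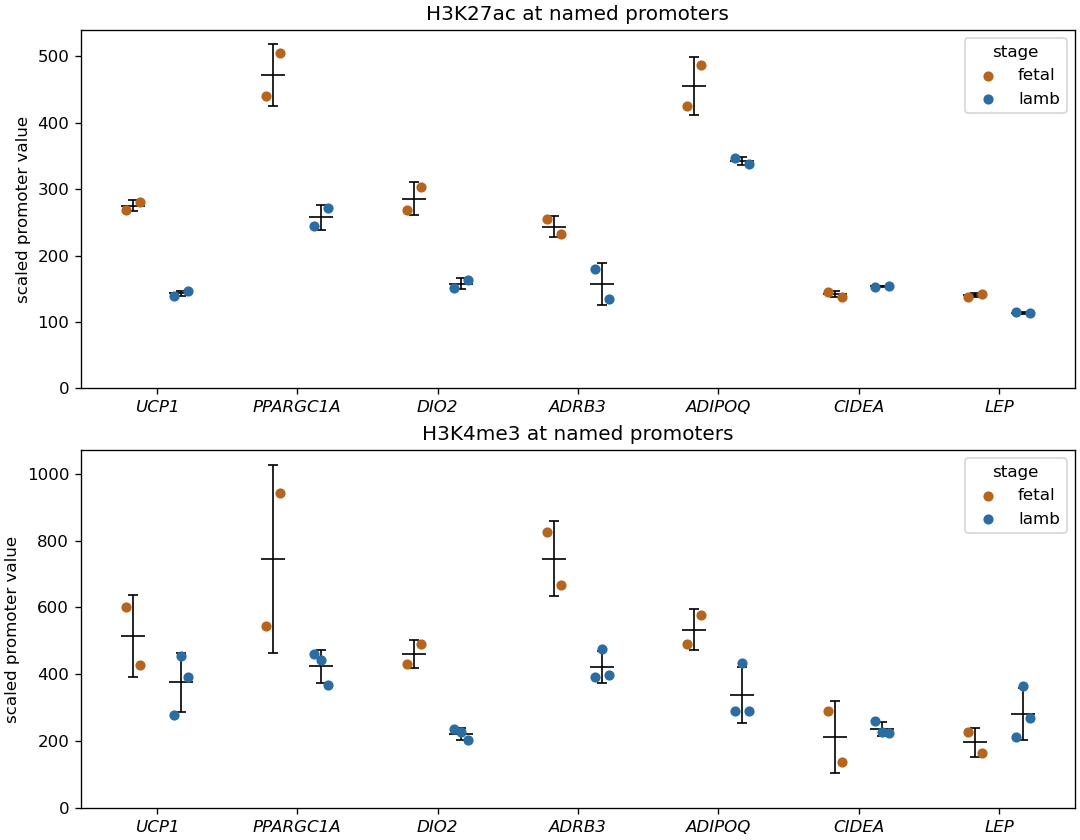
Scaled promoter values of H3K27ac and H3K4me3 at UCP1, PPARGC1A, DIO2, ADRB3, ADIPOQ, CIDEA and LEP, with a point per library and bars for the mean and SD of each stage (2 fetuses; 2 lambs for H3K27ac and 3 for H3K4me3). At UCP1, H3K27ac averaged 275 in fetuses and 143 in lambs.

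Of 24 measured brown fat and thermogenic genes, 6 were lower in lambs and 0 were higher, both among all promoters and adjusted over the list alone (median log2 change -0.24, camera adjusted p = 0.0449, or 0.605 with an estimated correlation and 0.0621 by fry). Beside UCP1, PPARGC1A, DIO2 and ADRB3, the group's calls included LHX8, a LIM homeobox regulator, which fell from 254 ± 68.8 to 125 ± 15.4 (log2 change -1.0). General adipocyte genes fell at 7 of 22 members (7 adjusted over the list alone, adjusted p = 0.0407, or 0.605 with an estimated correlation and 0.0621 by fry). Among them were the adiponectin receptor ADIPOR2 (-1.10), the lipid droplet coat gene PLIN1 (-0.93), the fatty acid carrier FABP4 (-0.93) and lipoprotein lipase LPL (-0.79). Fat synthesis genes fell at 6 of 22 members (6 adjusted over the list alone, adjusted p = 0.0421, or 0.605 with an estimated correlation and 0.226 by fry). Among them were ACACA, the carboxylase of fatty acid synthesis (-0.66), GPAM (-0.61), ACSS2 (-0.53) and ME1 (-0.74). Respiratory chain genes fell at 13 of 41 members (13 adjusted over the list alone, adjusted p = 0.00112, or 0.605 with an estimated correlation and 0.0621 by fry). They included ATP5B of the ATP synthase, from 452 ± 40.9 to 195 ± 44.2 (-1.23), ATP5G3 (-0.81), NDUFS7 (-0.72) and UQCRQ (-0.63). Without fetus 1 the adjusted p was 0.125 for the brown fat list, 0.0854 for the adipocyte list and 0.355 for fat synthesis, and without lamb 2 it was 0.0523, 0.104 and 0.184. Without lamb 1 the brown fat list reached 0.0778, and with the deposited scaling kept it reached 0.0557 and fat synthesis 0.0558. The respiratory chain list passed without any 1 of the 4 libraries, its highest adjusted p being 0.0075 without fetus 1.

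Genes of DNA replication and cell division and the HOX genes of positional identity were tested as further lists. Of 28 cell cycle genes, 9 fell and 1 rose (9 and 2 adjusted over the list alone, adjusted p = 0.0421, or 0.605 with an estimated correlation and 0.0621 by fry). Those that fell included PCNA, the sliding clamp of DNA polymerase, from 203 ± 8.21 to 114 ± 4.75 (-0.82), the helicase subunit MCM5 (-0.62), cyclin A2 CCNA2 (-0.74) and TYMS (-0.61). Of 26 HOX genes, 13 fell and 2 rose (14 and 2 adjusted over the list alone, adjusted p = 0.00883, or 0.605 with an estimated correlation and 0.0808 by fry). Losses included HOXA9 (-1.01), HOXD8 (-0.96), HOXC5 (-0.80) and HOXA3 (-0.70). Lymphocyte genes rose at 4 of 8 members and fell at 0 (5 adjusted over the list alone, median 0.62, adjusted p = 0.0182, or 0.605 with an estimated correlation and 0.0621 by fry). RHOH, a GTPase of blood cells, went from 116 ± 6.02 to 263 ± 2.48 (1.17), the T cell co-receptor CD8A rose by 1.19, CD3D by 0.71 and CD5 by 0.57. The cell cycle list did not pass without fetus 1 (0.0843), fetus 2 (0.0596) or lamb 2 (0.104), or with the deposited scaling (0.0765), and HOX did not pass without fetus 1 (0.0797).

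The other lists did not pass for H3K27ac as groups, though several of their members did. Stromal and preadipocyte genes split, with 5 higher and 6 lower of 22 (6 and 7 adjusted over the list alone, adjusted p = 0.958, with a positive median and a negative mean). The collagen gene COL3A1 fell from 686 ± 149 to 271 ± 20.9 (-1.32), as did VIM (-0.84), POSTN (-0.74) and DCN (-0.76). Developmental transcription factors had 6 higher and 7 lower of 35 (8 and 7 adjusted over the list alone, adjusted p = 0.586), with MEIS1 (-1.25), TBX18 (-1.11) and TBX3 (-0.81) lower. White fat genes had 2 higher and 4 lower of 16 (2 and 5, 0.413): HOXC10 (-0.68), TLE3 (-0.72) and RB1 (-0.46) fell and ZNF423, a preadipocyte regulator, rose by 0.50. Hormone receptor and signalling genes had 3 higher and 7 lower of 21 (3 and 7, 0.334), with the natriuretic peptide clearance receptor NPR3 (-1.12) and ADRA1A (-0.75) lower. Clock genes had 2 higher and 4 lower of 14 (3 and 5, 0.145), with NR1D1 (-0.90), DBP (-0.82), CLOCK (-0.64) and BHLHE40 (-0.77) lower. Chromatin modifiers had 3 higher and 6 lower of 30 (3 and 7, 0.334), with JARID2 (-0.80), SIRT1 (-0.84), EP300 (-0.60) and HDAC1 (-0.47) lower. Fatty acid oxidation genes had 0 higher and 3 lower of 19 (0 and 3, 0.093), including HADH (-0.64) and HADHA (-0.54).

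Smaller groups carried few H3K27ac calls. Citric acid cycle genes had 1 higher and 2 lower of 15 (1 and 2 adjusted over the list alone, adjusted p = 0.602), with IDH2 (-0.86) and SUCLA2 (-0.52) lower and SUCLG1 higher (0.45). Mitochondrial regulators had 0 higher and 3 lower of 13 (0 and 3, 0.602, with a positive median and a negative mean), namely PPARGC1A, MFN2 (-0.71) and SIRT3 (-0.38). Imprinted genes had 0 higher and 1 lower of 9 (0 and 1, 0.654, again with a positive median and a negative mean), the lower gene being PLAGL1 (-0.75). Macrophage genes had 1 higher and 1 lower of 10 (1 and 1, 0.208), the costimulatory ligand CD86 at 0.95 and the mannose receptor MRC1 at -0.44. Endothelial genes had 0 higher and 3 lower of 17 (0 and 3, 0.602), namely EMCN (-0.54), NOS3 (-0.46) and TEK (-0.37). Smooth muscle and pericyte genes had 2 higher and 1 lower of 8 (2 and 1, 0.32), with CNN1 (0.81), KCNMB1 (0.76) and RGS5 (-0.51). Skeletal muscle genes had 1 higher and 1 lower of 7 (1 and 1, 0.5), MYLPF at 0.54 and MYL1 at -0.89, and adrenal genes 1 higher and 0 lower of 5 (1 and 0, 0.334), the steroidogenic regulator NR5A1 at 1.32.

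The largest H3K27ac gains among named promoters were at OSR2 (from 27.1 ± 12.7 to 92.5 ± 21.5, log2 change 1.79), ISX (1.42), TCF24 (1.39), LY6E (1.37), LHX2 (1.37) and the vitamin D receptor VDR (from 80.8 ± 21.4 to 204 ± 8.50, 1.35). The largest losses were at the histone genes HIST1H2BD (-1.63) and HIST2H2BF (-1.45) and a 5S_rRNA copy (-1.49), all multi-copy families whose reads cannot be assigned with certainty, at AIMP1 (-1.55), at the transcription factor TCF4 (from 386 ± 2.41 to 136 ± 23.3, -1.51) and at COX20, an assembly factor of cytochrome oxidase (from 677 ± 79.3 to 258 ± 17, -1.39). In all, 3849 of 13222 promoters passed limma at an adjusted p under 0.05, with 1508 higher and 2341 lower in lambs. At every H3K27ac promoter said here to have risen or fallen, the lamb values did not overlap the fetal values. Chance gives this arrangement at 33.3% of unselected promoters. These promoters were selected by passing limma, and the largest changes also by having no overlap, so it adds no support. The split between gains and losses moved with scaling: column totals gave 2314 higher and 1789 lower (median change of all promoters 0.11), and the deposited scaling gave 167 higher and 4012 lower (median -0.30), while the medians of the 7 called lists kept their sign. The excess of losses was not seen without fetus 2, which gave 2839 higher and 2687 lower. The split was 2832 and 3014 without fetus 1, 268 and 1464 without lamb 2 and 142 and 1035 without lamb 1. Of the 109 promoters picked for naming that passed, 67 still passed without lamb 1 and 69 without lamb 2.

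H3K4me3 addressed which promoters gained or lost a transcription start mark over the same period. The largest loss in lambs among named promoters was at DIO1, a deiodinase of thyroid hormone, which fell from 561 ± 25.3 to 134 ± 49.9 (log2 change -2.13, SE 0.37, limma adjusted p = 0.000559). IDH3A of the citric acid cycle fell from 608 ± 306 to 175 ± 67.2 (-1.76, adjusted p = 0.00265), COX5A of cytochrome oxidase from 517 ± 210 to 167 ± 53.0 (-1.61, adjusted p = 0.00499), ACSL1, which activates fatty acids, from 588 ± 190 to 195 ± 41.9 (-1.58, adjusted p = 0.00306) and UQCRB of complex III from 967 ± 409 to 327 ± 35.4 (-1.50, adjusted p = 0.00145). Among the thermogenic genes, DIO2 fell from 461 ± 41.1 to 223 ± 17.4 (-1.04, adjusted p = 0.0308) and ADRB3 from 746 ± 113 to 422 ± 46.4 (-0.82, adjusted p = 0.0425). PPARGC1A had 744 ± 280.7 and 424 ± 48.7 (adjusted p = 0.0596), UCP1 515 ± 123 and 376 ± 89.3 (0.229), ADIPOQ 534 ± 60.3 and 339 ± 83.1 (0.0939), CIDEA 214 ± 107 and 237 ± 19.6 (0.645) and LEP 197 ± 43.6 and 282 ± 77.1 (0.296). The H3K4me3 promoter of DIO2 did not pass without fetus 2 (0.106), lamb 2 (0.195) or lamb 3 (0.418) or with column totals (0.0641), and the H3K4me3 promoter of ADRB3 did not pass without lamb 1 (0.0731), lamb 2 (0.223) or lamb 3 (0.447) or with column totals (0.0714).

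Respiratory chain genes fell in H3K4me3 at 7 of 39 members and rose at 0 (16 lower adjusted over the list alone, median log2 change -0.54, camera adjusted p = 3.76e-08, or 0.497 with an estimated correlation and 0.135 by fry). The losses included COX5A, UQCRB, cytochrome c CYCS (-1.04) and NDUFS4 (-0.93). The mitochondrial regulators passed camera as lower than other promoters (median -0.56, adjusted p = 0.0267, or 0.497 with an estimated correlation and 0.142 by fry), although 0 of 8 members passed singly, also adjusted over the list alone. With the replicate number as a block, and lamb 3 left out, this list did not pass camera (adjusted p = 0.0512). Of 30 cell cycle genes, CCNA2 (-0.87) and TTK (-0.80) fell and 0 rose (0 and 0 adjusted over the list alone, median -0.29, adjusted p = 0.0267, or 0.516 with an estimated correlation and 0.378 by fry). Of 22 chromatin modifiers, HDAC2 (-0.85) and JARID2 (-0.92) fell and 0 rose (3 lower and 1 higher adjusted over the list alone, median -0.33, adjusted p = 0.0206, or 0.516 with an estimated correlation and 0.202 by fry). The cell cycle list did not pass without fetus 2 (0.365) or lamb 1 (0.0604), chromatin modifiers without lambs 2 and 3 together (0.074), and mitochondrial regulators with the deposited scaling (0.0538).

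In the lists of immune cells, lymphocyte genes rose at 3 of 11 members and fell at 0 (7 higher adjusted over the list alone, median 1.13, adjusted p = 0.00137, or 0.516 with an estimated correlation and 0.158 by fry). These were the cytotoxic granule gene NKG7 (1.65) and the T cell receptor subunits CD3D (1.29) and CD3G (1.27). Macrophage genes rose at 2 of 10 members and fell at 0 (5 higher adjusted over the list alone, median 1.09, adjusted p = 0.00546, or 0.497 with an estimated correlation and 0.0941 by fry). These were CD68, from 145 ± 25.9 to 386 ± 61.2 (1.40), and the complement gene C1QA (1.69). With the deposited scaling, under which the median change of all promoters was -1.28, the medians of all H3K4me3 lists were negative, -0.15 for lymphocyte and -0.19 for macrophage genes. The promoters of both lists were weak in fetuses, with median values of 86.1 and 107 against 380 for all promoters. Among 10000 random lists matched on level, the lymphocyte median stood at percentile 72.5 and the macrophage median at 86.2.

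In the other lists, H3K4me3 calls were few and the groups did not pass. Brown fat genes had 1 higher and 3 lower of 26 (1 and 4 adjusted over the list alone, adjusted p = 0.162), with S100B higher (1.71) and SLC29A1 (-0.96), DIO2 and ADRB3 lower. Adipocyte genes had 1 higher and 3 lower of 21 (3 and 4, 0.168), with ACSL1, PLIN1 (-1.21) and PLIN4 (-1.04) lower and KLF15 higher (1.21). Fat synthesis genes had 1 higher and 1 lower of 21 (1 and 2, 0.184), ELOVL6 at 1.37 and ACLY at -1.04. Citric acid cycle genes had 0 higher and 2 lower of 15 (0 and 2, 0.0595), IDH3A and DLD (-0.89), and fatty acid oxidation genes 0 of 19 either way (0 and 0, 0.0573). Developmental transcription factors had 4 higher and 0 lower of 73 (0 and 0, 0.982, with a positive median against a negative camera direction), namely LHX5 (2.07), ZIC4 (1.26), NKX6-1 (1.14) and OTX2 (1.02), and HOX genes 1 higher and 0 lower of 31 (0 and 0, 0.162), HOXB13 at 1.27. The developmental list passed as higher without fetus 1 (0.00523) and as lower without fetus 2 (4.02e-05). Hormone receptor genes had 0 higher and 2 lower of 20 (0 and 2, 0.342), DIO2 and ADRB3, and stromal genes 0 higher and 1 lower of 22 (0 and 0, 0.771, with a negative median and a positive mean), COL3A1 at -0.89.

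Further lists gave 0 or 1 H3K4me3 calls each. Clock genes had 1 higher of 12 (1 adjusted over the list alone, adjusted p = 0.499), RORA at 1.30, endothelial genes 1 higher of 17 (2 higher and 1 lower adjusted over the list alone, 0.644, with a negative median and a positive mean), ERG at 1.55, and adrenal genes 1 higher of 5 (1, 0.499), CHGB at 1.85. White fat genes had 0 of 14 (0, 0.881), imprinted genes 0 of 12 (0, 0.982), smooth muscle genes 0 of 8 (0, 0.298), erythroid genes 0 of 6 (0, 0.204) and skeletal muscle genes 0 of 6 (3 higher adjusted over the list alone, 0.184). In these 5 lists the smallest limma adjusted p was 0.0634, at FST.

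Outside the lists, the largest H3K4me3 gains were at 4 copies of 5S_rRNA (3.79, 3.43, 3.29 and 2.83), a multi-copy family whose reads cannot be assigned with certainty, at CYP4B1, a cytochrome P450 (from 47.7 ± 20.9 to 319 ± 136, 2.67), and at CCDC73 (2.62). The ultraconserved element uc_338 was among the largest losses (-1.54). In all, 1322 of 12922 promoters passed limma, 1077 higher and 245 lower in lambs. Gains lay at weak promoters: of the 4 level groups of promoters, the weakest held 604 gains and 1 loss and the strongest 8 gains and 165 losses. At the named H3K4me3 promoters that passed, except NKX6-1, the lamb values did not overlap the fetal values, which chance gives at 20% of unselected promoters. Since these promoters were selected, this adds no support. Column totals gave 1337 calls and a median change of 0.13 over all promoters. The deposited scaling moved all promoters nearly alike and gave 55 higher and 5623 lower, so that gains smaller than this move changed sign whatever the gene, among them KLF15, HOXB13, ZIC4, OTX2, NKX6-1, CD3G, oar-mir-21 and RBMS2. The excess of gains was not seen without fetus 1, which gave 2730 higher and 2950 lower. The split was 608 and 102 without fetus 2, 1554 and 275 without lamb 1, 40 and 10 without lamb 2 and 8 and 4 without lamb 3. Without lambs 2 and 3 together limma called 0 (102 at an unadjusted p under 0.05). Of the 59 promoters picked for naming that passed, 57 still passed without fetus 1, 34 without fetus 2, 48 without lamb 1, 15 without lamb 2, 6 without lamb 3 and 0 without lambs 2 and 3 together. The thinned libraries, each at 2476065 promoter reads, gave 953 calls, 801 of them higher.

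H3K27me3 addressed which promoters gained or lost Polycomb silencing. Among developmental regulators, MSX2, a homeobox factor of limb and skull development, fell from 891 ± 18.0 to 373 ± 14 (log2 change -1.25, SE 0.18, limma adjusted p = 0.000291). GATA4, a factor of heart and endoderm development, fell from 923 ± 74.8 to 429 ± 87.4 (-1.12, adjusted p = 0.000945). Of 72 developmental transcription factors measured, 31 fell and 0 rose (47 lower adjusted over the list alone, median -0.57, camera adjusted p = 1.60e-10, or 0.510 with an estimated correlation and 0.09 by fry). Of 26 HOX genes, 9 fell and 0 rose (10 lower adjusted over the list alone, median -0.51, adjusted p = 0.00291, or 0.510 with an estimated correlation and 0.0303 by fry). Losses included HOXD13, from 1588 ± 1.89 to 912 ± 150 (-0.81), HOXD10 (-0.97), HOXC12 (-0.83) and HOXB13 (-0.69). Both lists passed camera at the preset correlation without any 1 of the 4 libraries and under each scaling.

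At the thermogenic and adipocyte genes the H3K27me3 test found few changes. UCP1 had 400 ± 42.3 in fetuses and 447 ± 15.5 in lambs (adjusted p = 0.614), ADRB3 207 ± 12.1 and 279 ± 68.4 (0.300), PRDM16, a regulator of brown fat identity, 79.0 ± 2.47 and 143 ± 56.8 (0.179), CIDEA 121 ± 33.2 and 131 ± 22.6 (0.826) and LEP 484 ± 23.2 and 380 ± 22.7 (0.241). In the brown fat list 3 of 15 genes fell and 0 rose (4 lower adjusted over the list alone, camera adjusted p = 0.589), LHX8 (-0.95), ZIC1 (-0.88) and ESRRG (-0.81). White fat genes had 0 of 9 (0, 0.564) and adipocyte genes 0 of 7 (0, 0.564), and the smallest limma adjusted p in these lists was 0.0542, at TCF21. Stromal genes had 2 lower of 11 (2, 0.253), GSN, an actin-severing protein, and fibronectin FN1 (-1.12), and hormone receptor genes 1 lower of 14 (1, 0.724), the leptin receptor LEPR (-0.62). Imprinted genes had 0 of 8 (0, 0.900, with a negative median and a positive mean).

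Markers of other cell types moved in H3K27me3 at single genes. Macrophage genes had 2 higher and 1 lower of 6 (2 and 1 adjusted over the list alone, adjusted p = 0.596), EMR1 (1.13) and C1QC (1.22) against CD14 (-1.31), and lymphocyte genes 1 higher and 0 lower of 11 (1 and 0, 0.596), NKG7 at 1.04. Endothelial genes had 0 higher and 2 lower of 7 (1 and 4, 0.589), FLT1 (-0.80) and SOX17 (-1.05). A single lower gene was called in each of the lists of smooth muscle (NOTCH3 -0.89, of 9, 0 adjusted over the list alone, 0.596), skeletal muscle (ACTA1 -0.67, of 11, 1, 0.589), erythroid (TAL1 -0.78, of 6, 1, 0.542), mesothelial (LRRN4 -0.72, of 6, 1, 0.589) and kidney genes (of 10, 1 lower and 2 higher, 0.966, with a negative median and a positive mean). The nerve list had 1 lower of 9 (2, 0.542), and adrenal genes had 0 of 8 (0, 0.589), with a smallest limma adjusted p of 0.119 at TH.

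The largest H3K27me3 losses among named promoters were at GSN, from 187 ± 6.91 to 22.1 ± 19.6 (-3.34), the adenosine receptor ADORA2B (-3.31), FXYD5 (-2.14), the immunoproteasome subunit PSMB9 (-2.11), CAST (-2.10) and MINK1 (-2.09). Large gains lay at coagulation factor F10, from 38.7 ± 7.09 to 156 ± 98.6 (1.84), DAP12 (1.80), C1orf68 (1.80), SLC44A4 (1.75) and GABRD (1.72). In all, 839 of 6334 promoters passed limma, 280 higher and 559 lower in lambs. At the named promoters that passed the stages did not overlap, which chance gives at 33.3% of unselected promoters. Since these promoters were selected, this adds no support. Column totals gave 435 higher and 368 lower (median change of all promoters 0.13). The deposited scaling gave 134 and 406, and DESeq2 gave 25 and 188. The count was 1405 without lamb 1, 148 without fetus 1, 100 without fetus 2 and 0 without lamb 2 (1797 at an unadjusted p under 0.05), so that of the 59 promoters picked for naming that passed, 49, 15, 11 and 0 still passed in those settings.

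**Figure D2:**
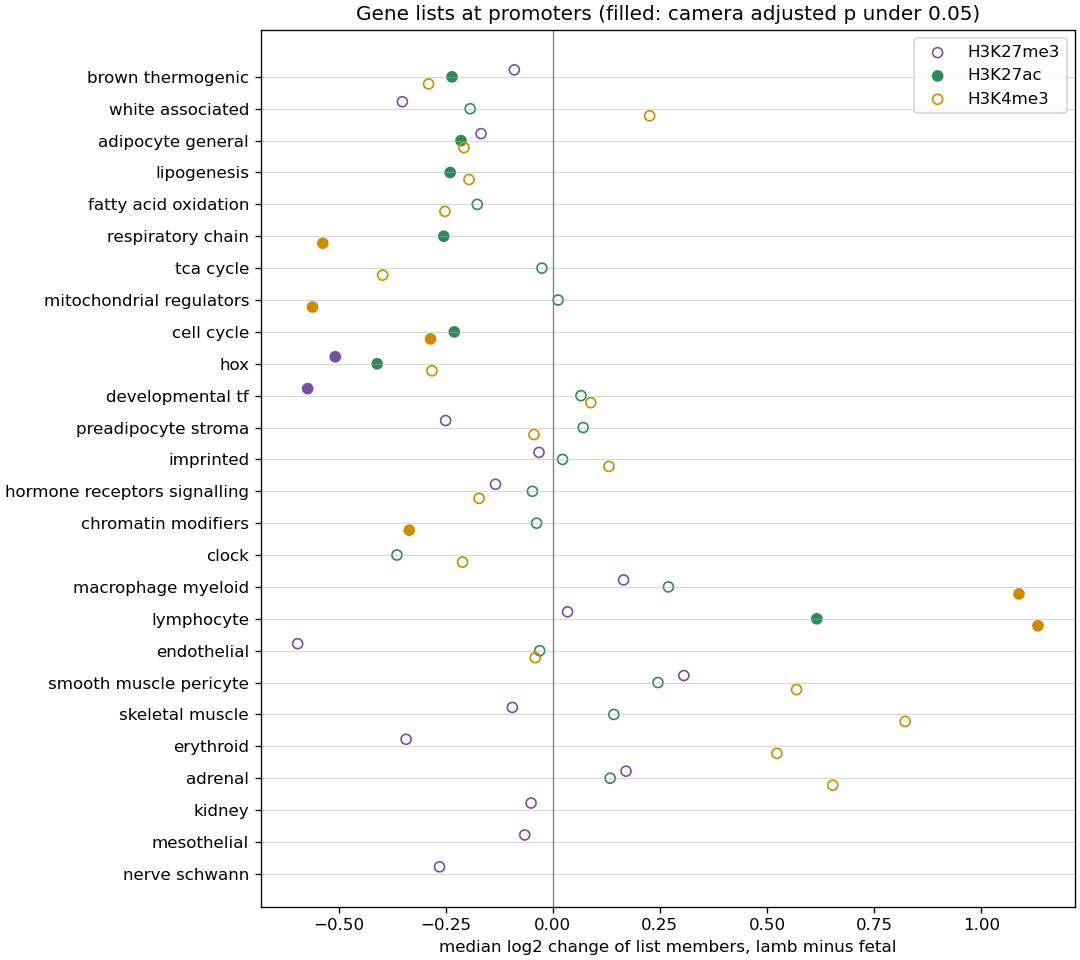
Median log2 change (lamb minus fetus) of the promoters in each gene list for H3K27ac, H3K4me3 and H3K27me3, with filled symbols where the camera adjusted p was under 0.05 at the preset correlation. No list passed camera with an estimated correlation, a setting to which so few libraries leave little power. Developmental transcription factors and HOX genes stand at -0.57 and -0.51 in H3K27me3, and with the deposited scaling, which moves the median of all H3K4me3 promoters to -1.28, all H3K4me3 medians are negative.

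Calls were also compared between marks gene by gene. The marks come from the same animals, so counts expected from independent calls are not the values without a stage difference, and the p below do not test for a link between the marks at the stage change. Regrouping the 4 shared animals across stages gave H3K27ac and H3K4me3 a rho of 0.64 in one split, above the 0.59 of the stages, and 0.05 in the other. The covariance, which keeps the size of the changes, was 0.048 and 0.0022 in these splits and 0.14 for the stages. Lower H3K27ac and lower H3K4me3 were called together at 189 genes, against 54.8 expected if the calls were independent (Fisher's exact test, adjusted p = 4.7e-75), among them DIO1 (H3K27ac -0.86), ACSL1 (-0.60), PLIN1 (-0.93) and the metalloprotease gene ADAM19 (-0.79, with -1.26 in H3K4me3). Both marks were higher at 132 genes against 37.5 expected (adjusted p = 6.0e-40), among them OCIAD2 (1.04 and 1.74) and the transporter SLC10A6 (0.81 and 1.94), with a Y_RNA and a 7SK copy, both of multi-copy families. H3K27ac rose while H3K27me3 fell at 117 genes against 66.5 expected (adjusted p = 2.6e-12). Among them were the urokinase receptor PLAUR (1.10 and -1.49), S100A6 (0.57 and -1.83), FAM149A (1.03 and -1.18) and SLAIN1 (0.99 and -1.61). Level was not matched in these counts. Of 4 groups by promoter level, the weakest held 558 gains and 83 losses of H3K27ac. The strongest held 22 gains and 403 losses of H3K27me3, so the excess cannot be separated from level here. Overlapping regions of these marks went the other way: 55 such pairs against 90.3 expected, and 154 higher in both against 33.5. These expected counts pool X, where H3K27me3 mostly fell, with the autosomes, where it mostly rose. The contrast with promoters was not separated from this pooling. H3K4me3 and H3K27me3 both rose at 27 genes against 7.54 expected (adjusted p = 4.0e-10), including C1orf68 (2.26 and 1.80) and MUC12 (1.63 and 0.64).

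H3K27ac fell where H3K4me3 rose at 16 genes against 106 expected (adjusted p = 5.4e-32), including GPR116 (-0.42 and 1.55), oar-mir-30a (-0.38 and 1.38), oar-mir-21 (-0.44 and 1.06) and RBMS2 (-0.48 and 1.22), and the reverse occurred at 0 genes against 19.5 expected (adjusted p = 4.5e-09). H3K4me3 rose where H3K27me3 fell at 42 genes against 77.3 (adjusted p = 1.2e-06), including DBX1 (1.56 and -0.79) and SLC6A5 (1.43 and -0.62). H3K27ac and H3K27me3 both fell at 9 genes against 22 (adjusted p = 0.00182), including LHX8 and MECOM (-0.92 and -1.40). The remaining pairs did not pass: both rose at 7 genes (9.8 expected, 0.405), including FCGR3A (1.11 and 0.86), H3K27ac fell as H3K27me3 rose at 5 (3.24, 0.405), and H3K4me3 fell with higher or lower H3K27me3 at 1 (0.295, 0.344) and 2 genes (3.03, 0.757).

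Over all genes measured in both marks, the change of H3K27ac correlated with that of H3K4me3 (Spearman's rho 0.58, Pearson's r 0.51, 10109 genes), and H3K4me3 with H3K27me3 (0.39 and 0.40, 3522 genes), while H3K27ac and H3K27me3 gave -0.04 and -0.02 (2297 genes). These are correlations across genes, which are not independent replicates, and no p was computed. Regrouping the same 4 animals gave rho values of 0.64 and 0.05 for the first pair, 0.31 and -0.26 for H3K27ac with H3K27me3, and 0.38 and -0.12 for H3K4me3 with H3K27me3. Without fetus 2 the H3K27ac and H3K4me3 value was 0.36, and H3K27ac with H3K27me3 moved from -0.16 without lamb 1 to 0.08 without lamb 2.

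Peak regions extended the comparison beyond promoters. For H3K27ac, 12144 of 87271 regions passed edgeR, 3906 higher and 8238 lower in lambs. The strongest gains were at 76922051 to 76922900 on chromosome X of the Oar_v3.1 build, from 159 and 107 reads in fetuses to 826 and 610 in lambs (log2 change 2.47, SE 0.19), at 76684901 to 76685700 on X (2.40), at 58261201 to 58262250 on chromosome 11 (2.13) and at 28112751 to 28113700 on chromosome 20 (2.07). The losses were led by 67333501 to 67334350 on chromosome 13, with 197 and 85 reads in fetuses and 0 in both lambs (at least 44.5-fold lower, against a floor of 3 reads per library), and included 50048501 to 50049350 on X (-2.75), 4886501 to 4887050 on chromosome 10 (-2.53) and part of the mitochondrial genome (-3.27). The lamb libraries held medians of 333 and 271 reads per region, and why the chromosome 13 region had 0 was not tested. Column totals gave 6309 higher and 6369 lower. The count was 31372 without fetus 1, 2648 without lamb 1 and 4135 without lamb 2.

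For H3K27me3, 15671 of 106036 regions passed edgeR, 8037 higher and 7634 lower in lambs. Chromosome X held most of the losses. Of 23609 regions tested on X, 5997 fell and 46 rose (median log2 change -0.71), while on the autosomes 1635 fell and 7991 rose (median 0.31). X held 49.5% and 48.7% of the reads in regions in the fetuses, 29.7% in lamb 1 and 41.3% in lamb 2. When the scaling was taken from regions outside X and the mitochondrial genome, which moved the median change of all regions to -0.23, 11945 X regions fell and 25 rose and 3905 autosomal regions fell and 2966 rose. Regions with no reads in a stage led the changes: 60324901 to 60325950 on X had 0 reads in both fetuses and 14 and 47 in lambs (at least 12.7-fold higher), its neighbours 60326451 to 60327400 and 60330501 to 60331100 were at least 10.4-fold and 7.87-fold higher, and 179861301 to 179862050 on chromosome 3 had 23 and 31 reads in fetuses and 0 in lambs (at least 7.43-fold lower). Medians per region were 33 and 30 reads in fetuses and 32 and 28 in lambs, and the cause of the counts of 0 was not tested. The other leading regions were 57842201 to 57842800 on chromosome 14, with 2 and 0 reads in fetuses and 26 and 14 in lambs, and the losses at 133218901 to 133219950 on X (23 and 45 against 2 and 0), 2186651 to 2187500 on chromosome 2 (31 and 32 against 2 and 1) and 94657151 to 94657900 on chromosome 4 (24 and 19 against 1 and 1). RLE scaling gave 6884 higher and 9338 lower regions. Column totals gave 15250 higher and 3329 lower regions (median change of all regions 0.27), and DESeq2 805 and 5347. The count was 53 without fetus 1, 34 without fetus 2 and 41322 without lamb 2.

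**Figure D3:**
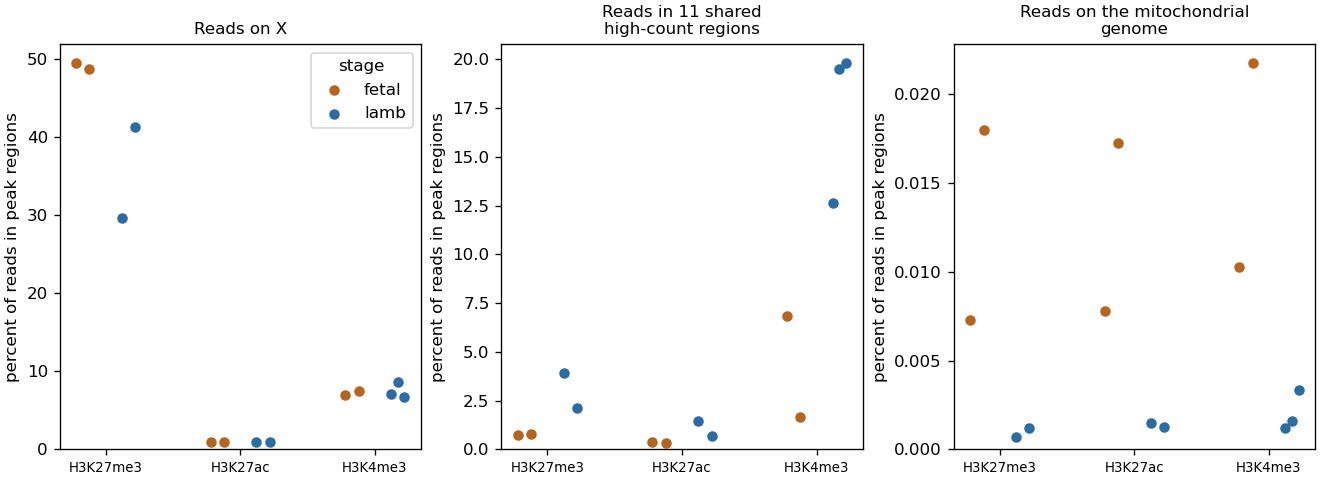
Percent of each library's region reads on chromosome X, in the 11 high-count regions shared by the marks, and on the mitochondrial genome, with a point per library of each mark and stage. In H3K27me3 the share on X is 49.5% and 48.7% in fetuses and 29.7% and 41.3% in lambs.

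For H3K4me3, edgeR called 76 of 66207 regions, 35 higher and 41 lower in lambs, against 15000 at an unadjusted p under 0.05. A region on chromosome 1 from 28161601 to 28168550 fell from 2901 and 4412 reads in fetuses to 307, 171 and 141 in lambs (log2 change -3.06, SE 0.36, adjusted p = 0.00443), and 55350251 to 55351350 on chromosome 11 (-2.94), 247020801 to 247023100 on chromosome 2 (-3.07) and part of the mitochondrial genome (-3.18) also fell. The gains were led by 20708401 to 20709200 on chromosome 16 (4.30), where a 5S_rRNA copy lies, 105034401 to 105035200 on chromosome 4 (4.25), 253130551 to 253131400 on chromosome 1 (4.25) and 45264051 to 45265000 on chromosome 17 (4.21). The shared high-count regions held 6.84% and 1.67% of H3K4me3 reads in fetuses and 12.6%, 19.5% and 19.8% in lambs. Column totals gave 137 higher and 40 lower regions (median change of all regions 0.15), RLE scaling 3 and 10, scaling from regions outside X and the mitochondrial genome 699 and 175, and DESeq2 1288 and 5682, and 10 regions passed when the mitochondrial and shared high-count regions were left out. The count was 17114 without fetus 1 (8712 higher and 8402 lower), 9614 without fetus 2 (6649 and 2965), 4600 without lamb 1 (579 and 4021), 0 without lamb 2 (6705 at an unadjusted p under 0.05) and 64 without lamb 3.

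Overlap was counted between the regions of each pair of marks. By at least 1 bp, 39.7% of H3K27ac regions overlapped an H3K4me3 region and 48.6% of H3K4me3 regions an H3K27ac region. H3K27me3 regions were overlapped by 5.41% of H3K27ac and 33.2% of H3K4me3 regions. On chromosome X, 96.0% of 10036 H3K4me3 regions and 89.9% of 1025 H3K27ac regions overlapped an H3K27me3 region, and 73.9% of those H3K27ac regions an H3K4me3 region. X held 23671 H3K27me3 regions and 43.7% of the length of all H3K27me3 regions, so a high overlap there can follow from coverage alone. The overlap to be had from coverage was not computed.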

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

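The tests of mitochondrial reads, by mark and by animal, were chosen only after the result was seen. Mitochondrial DNA carries no histones and lies outside what the comparisons measure, yet its regions drew a larger share of reads in fetuses than in lambs in every mark. The share was 13.4-fold higher for H3K27me3 (0.0126% ± 0.00757 against 0.00094% ± 0.000371, n = 2 and 2), 9.20-fold for H3K27ac (0.0125% ± 0.00671 against 0.00136% ± 0.000142, n = 2 and 2) and 7.86-fold for H3K4me3 (0.016% ± 0.00812 against 0.00204% ± 0.00115, n = 2 and 3). All fetal libraries lay above all lamb libraries. In the same order of marks, the lowest fetal share was 6.05, 5.32 and 3.07 times the highest lamb share. An exact two-sided permutation test in these designs cannot go below p = 0.333, 0.333 and 0.2.

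A source that depends on the antibody is argued against by the likeness of the ratios, the largest being 1.71 times the smallest. Mitochondrial DNA carried along with each animal's chromatin may be a source and remains open: fetus 2 had the higher share in 3 of 3 marks, at 2.47, 2.22 and 2.12 times fetus 1, but lamb 2 was at 1.77 and 1.32 times lamb 1 in H3K27me3 and H3K4me3 and at 0.862 in H3K27ac. Whether the tissue held more mitochondrial DNA before birth or the chromatin of each stage was prepared differently cannot be separated here, since the labels give no preparation batch. The developmental stage itself remains an open explanation that was not tested further.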

How the results depend on the processing

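The deposited scaling, the authors' test at 0.05, scaling outside X, leaving out high-count regions or lambs 2 and 3, edgeR on recovered reads and the 4 H3K4me3 libraries without a block were tests chosen only after the results were seen. Counts not listed here stayed within 1.5 times the reported ones, though their split into higher and lower moved with scaling. Single promoters, regions and lists not listed crossed the threshold in some settings without turning. For promoter tables the planned fit without a filter is the reported fit, since none was applied, and a mean of 20 reads removed no H3K27ac promoter. Where no cause is given, the cause was not tested.

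Counts of called promoters (839 for H3K27me3, 3849 for H3K27ac and 1322 for H3K4me3) moved as follows. DESeq2 called 213 H3K27me3 and 2349 H3K4me3 promoters. The deposited scaling called 540 for H3K27me3 and 5678 for H3K4me3, and a threshold of 0.01, stricter by construction, left 268, 1965 and 198. Leaving out a library gave 0 (without lamb 2, 1797 at an unadjusted p under 0.05) to 1405 (without lamb 1) for H3K27me3, 1177 (lamb 1) to 5846 (fetus 1) for H3K27ac and 12 (lamb 3) to 5680 (fetus 1) for H3K4me3. Without lambs 2 and 3 limma called 0 H3K4me3 promoters (102 at an unadjusted p under 0.05).

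Counts of called regions (15671, 12144 and 76 in the same order) moved with the test to 6152 for H3K27me3 and 6970 for H3K4me3 under DESeq2. A threshold of 0.01 left 3105, 3978 and 7. The authors' test gave 4192 at 0.01 for H3K27me3, and 5948 at 0.05 and 570 at 0.01 for H3K4me3. H3K4me3 regions numbered 13 with RLE scaling, 177 with column totals, 874 with scaling outside X and the mitochondrial genome, 10 without mitochondrial and high-count regions and 2 without lambs 2 and 3. Leaving out a library gave 34 (fetus 2) to 41322 (lamb 2) for H3K27me3, 2648 (lamb 1) to 31372 (fetus 1) for H3K27ac and 0 (lamb 2, 6705 at an unadjusted p under 0.05) to 17114 (fetus 1) for H3K4me3.

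A block on the replicate number gave 25434 H3K27ac regions, and without lamb 3 it gave 3 H3K4me3 promoters and 171 regions, against 12 promoters and 64 regions in the same 4 libraries without it. The differences between replicates 1 and 2 correlated between stages, across genes, at 0.0988 for H3K27me3, 0.277 for H3K27ac and -0.394 for H3K4me3. The sign differs between marks, so the numbers have no order common to all marks. An order within a single mark is not excluded.

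Called lists numbered 2 for H3K27me3, 7 for H3K27ac and 6 for H3K4me3. With an estimated correlation camera called 0, 0 and 0, and fry called 1, 0 and 0. The deposited scaling left 4 for H3K27ac. Leaving out a library gave 2 (fetus 1) to 8 (fetus 2) for H3K27ac and 5 (lamb 1) to 13 (fetus 2) for H3K4me3. The developmental list of H3K4me3 had adjusted p from 4.02e-05 (lower, without fetus 2) to 0.983 (without lamb 1), and turned to higher without fetus 1 (0.00523), without lamb 1, with fry (0.803) and with column totals (0.97). Other lists that turned passed in neither direction where they turned. In H3K4me3 these were stromal (0.554) and endothelial genes (0.961) with fry, white fat genes with the deposited scaling (0.956) and the block (0.999), and imprinted (0.733) and erythroid genes (0.749) without lambs 2 and 3. With a library left out they were, by the range of adjusted p, imprinted (0.63 to 0.963), smooth muscle (0.479 to 0.72), skeletal muscle (0.309 to 0.963) and kidney genes (0.656 to 0.963) in H3K27me3, and developmental (0.274 to 0.785), stromal (0.43 to 0.857), imprinted (0.356 to 0.96) and endothelial genes (0.0596 to 0.907) in H3K27ac. In H3K4me3 they were white fat (0.577 to 0.989), imprinted (0.577 to 0.98), hormone receptor (0.0224, lower, to 0.952) and adrenal genes (0.139 to 0.543). Medians of lists follow the scaling too: with the deposited scaling all H3K4me3 medians and all H3K27ac medians but that of lymphocyte genes were negative.

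Among genes called in at least 1 of a pair of marks, rho turned to 0.089 for H3K27ac with H3K27me3 and was 0.759 for H3K4me3 with H3K27me3, or 0.354 there over all genes without lambs 2 and 3. Leaving out an animal gave 0.363 (fetus 2) to 0.63 (fetus 1) for H3K27ac with H3K4me3, -0.157 (lamb 1) to 0.0819 (lamb 2) for H3K27ac with H3K27me3 and 0.306 (lamb 2) to 0.39 (lamb 3) for H3K4me3 with H3K27me3.

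With the deposited scaling, which moved all H3K4me3 promoters nearly alike (median change -1.28), each smaller gain turned to a loss, so that a turn says nothing about the gene. Among picked H3K4me3 promoters called in either scaling these were CIDEA (-1.04), KLF15 (-0.0736), HOXB13 (-0.0111), ZIC4 (-0.0267), OTX2 (-0.27), NKX6-1 (-0.14), CD3G (-0.00621), oar-mir-21 (-0.22) and RBMS2 (-0.0575). Those not called in either included LEP (-0.79), ZNF423 (-0.26), THRSP (-0.56), PC (-0.31), HOXD12 (-0.098), HOXC12 (-0.30), PI16 (-0.0357), GSN (-0.0677), IGF2R (-0.23), DIO3 (-0.53), CREBBP (-0.00709), NFIL3 (-0.29), ITGAM (-0.19), LYVE1 (-0.0983), VWF (-0.61), TAGLN (-0.22), CSPG4 (-0.60), KCNMB1 (-0.0631), MYOD1 (-0.13), RYR1 (-0.42), ACTA1 (-0.25), MYL1 (-0.73), EPOR (-0.23), TAL1 (-0.88), ALAS2 (-0.76), NR5A1 (-0.40) and CHGA (-0.63). In H3K27ac, with a median change of -0.30, they were CIDEA (-0.20), MEST (-0.0316), IGF2R (-0.15), TTN (-0.0043) and STAR (-0.19). Without lambs 2 and 3 MYL1 turned in H3K4me3 (-0.0253). Picked promoters kept their direction and their side of the threshold in 727 comparisons for H3K27ac, 566 for H3K27me3 and 622 for H3K4me3 under the settings of the original design that keep all libraries, and weakened past it in 16, 32 and 72. With 1 library left out they did so in 397, 256 and 400 and weakened in 94, 161 and 135. None of those that turned with a library left out was called in the full set: in H3K27me3 CIDEA (-0.15 to 0.39), ITGAM (-0.15 to 0.47), LMOD1 (-0.026 to 1.53), CHGA (-0.0782 to 0.63) and KRT8 (-0.38 to 0.0586), and in H3K4me3 CIDEA (-0.29 to 0.77), DIO3 (-0.20 to 1.69), MYL1 (-0.0912 to 1.18), NR5A1 (-0.19 to 1.96) and CHGA (-0.25 to 1.56). Simulated 1.5-fold changes were recovered at 7.46% of H3K27me3, 0% of H3K4me3 and 40.3% of H3K27ac promoters. H3K27me3 had the fewest reads per promoter (medians of 43 to 54), and H3K4me3 the largest spread between fetuses (SD of the log2 difference 0.757, against 0.439 for H3K27me3 and 0.325 for H3K27ac). How much each limits the calls was not compared.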

Other observations

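The tests of chromosome X by scaling and by sex and of H3K4me3 background in lambs 2 and 3 were chosen only after the result was seen. Promoters with a high mean level over the libraries of both stages tended to lose each mark and weak ones to gain it. Each gene list was therefore also set beside random lists of like mean level. In H3K27ac the medians of cell cycle genes (percentile 0.01), HOX genes (0.06), clock genes (0.23), brown fat genes (0.65), respiratory chain genes (0.76) and fat synthesis genes (0.81) lay below nearly all of the 10000 matched lists, as did those of white fat genes (1.39), while general adipocyte genes stood at 16.6 and lymphocyte genes at 99.9. In H3K4me3 respiratory chain genes stood at 0.1, brown fat genes at 0.67, cell cycle genes at 1.21, citric acid cycle genes at 1.69, mitochondrial regulators at 7.86, chromatin modifiers at 33.6 and developmental transcription factors at 99.8. In H3K27me3 developmental transcription factors stood at 0.06, endothelial genes at 1.29 and HOX genes at 1.65. If members varied independently, a loss common to promoters of like level would not account for the whole of the developmental and HOX losses. The random lists were drawn as unrelated genes, however, so the percentiles leave out correlation between members. With an estimated correlation camera gave both lists an adjusted p of 0.510. So few libraries leave that setting little power, so it does not decide whether correlation accounts for these losses. Endothelial genes did not pass camera at the preset correlation either (0.589).

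Of 5098 overlapping pairs of H3K27ac and H3K27me3 regions, 154 rose in both marks against 33.5 expected from the separate counts and 108 fell in both against 83.1, while 55 rose in H3K27ac and fell in H3K27me3 against 90.3. For H3K27ac and H3K4me3, 33 pairs fell in both against 7.56 expected and 4 rose in both against 0.191. Neighbouring regions are not independent and the marks share animals, so these expected counts are not values without a stage difference, and no p was computed. They also pool X, where 5997 H3K27me3 regions fell and 46 rose, with the autosomes, where 1635 fell and 7991 rose. An excess of pairs that moved alike can come from such pooling, which was not separated. At promoters H3K27ac and H3K27me3 went the other way, with 117 genes higher in H3K27ac and lower in H3K27me3 against 66.5 expected. The region pairs were counted under the reported scaling. Scaling from regions outside X and the mitochondrial genome lowered the autosomal H3K27me3 gains from 7991 to 2966.

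Lower H3K27me3 on chromosome X in lambs is not accounted for by scaling, since X regions fell further than autosomal regions in all 4 pairings of a lamb with a fetus (the smallest difference on the log2 scale being -0.619). Weaker enrichment in the lamb libraries remains open: against autosomal regions with the same fetal reads per kb, X regions differed by -0.972 and -0.887 in lamb 1 but by -0.264 and -0.182 in lamb 2, and the last did not clear the limit of 0.2. The median reads per kb of X regions was 1.35 and 1.42 times that of autosomal regions in the fetuses, 0.933 in lamb 2 and 0.479 in lamb 1. Male lambs beside female fetuses, without the inactive X that carries this mark, may therefore be a reason, which the labels cannot settle because they give no sex. The lambs differed from each other, which male sex in both would not account for by itself. In H3K27ac the ratio was 0.981 and 0.977 in fetuses and 0.882 and 0.844 in lambs. In H3K4me3 it was 0.705 and 0.956 in fetuses and 0.713, 0.877 and 0.664 in lambs. Developmental stage remains an open explanation that was not tested apart from the animals.

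Higher H3K4me3 at 1077 promoters in lambs was measured mainly at promoters that were weak in fetuses, with a median value of 87.4 against 380 for all promoters. The lower depth of lambs 2 and 3 is argued against by thinning every library to 2476065 reads, which still gave 801 higher promoters. Background in lambs 2 and 3 remains open: the median rise of lamb 1 was 0.575 of the mean of theirs (1.07 against 1.99 and 1.71), but lamb 1 took part in the calling of these promoters, and without lambs 2 and 3 limma called 0 promoters (102 at an unadjusted p under 0.05). Background that raises weak promoters alike in all lambs could account for the gains at lymphocyte (percentile 72.51) and macrophage genes (86.21), which lay within the range of random lists of like level. A change in the cell make-up of the tissue with age remains open and was not tested.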
